A study of Arabidopsis thaliana with 12 samples.

How the data were processed

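Transcript abundance in Arabidopsis thaliana seedlings was compared on 2-colour cDNA arrays of EST clones (expressed sequence tags, short cDNA reads that each stand for part of a transcript). Per the labels, seedlings were treated for 1 h, and each array held a test RNA in 1 channel and a control RNA in the other. The treatments were trifluoperazine (TFP, a phenothiazine) and W7 (a naphthalenesulfonamide), which are both calmodulin antagonists, with the solvent DMSO as the control. In some experiments the seedlings were pretreated with lanthanum ions (La), a blocker of calcium channels. Doses were not given in the sources used here.

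The design had 4 experiments of 3 arrays each: TFP against DMSO, W7 against DMSO, W7 against W7 after La (written W7 against La plus W7), and W7 after La against DMSO after La (written La plus W7 against La plus DMSO). The deposited text calls the 3 arrays of an experiment independent biological repeats. Ratios were always taken as the first named treatment over the second, from the RNA and dye that the labels give for each channel. The test RNA carried Cy5 on TFP arrays 1 and 2, W7 array 2 and La plus W7 arrays 2 and 3, and Cy3 on the others, so dyes were not balanced within any experiment. The 3 arrays of W7 against La plus W7 all had the test RNA in Cy3 in the labels and in the scanner headers, although the design text speaks of a dye swap in each experiment.

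The authors deposited scanner output per array, and the values used from it were raw spot intensity and local background of both channels, with no background subtraction and no normalization per the file headers. The authors also deposited a table of 1 value per spot and array, which matched a linear ratio of the test to the control channel: its column medians lay between 0.95 and 1.01, and its log2 values correlated at 0.98 to 1.00 with the loess ratios computed here. How the authors normalized that ratio is not given in the sources used here. The scanner files under W7 against DMSO arrays 1 and 2 held identical values. Their raw ratios had a Spearman correlation of 0.89 with the authors' ratio for array 1 and of 0.31 with that for array 2, and the dyes in the header were those of array 1. They were therefore counted as 1 sample, array 1, and the ratios of W7 array 2 entered only through the deposited table. The fit thus used 11 of the 12 arrays, with n = 2 for W7 against DMSO, where 12 arrays had been planned.

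Of the spots, 11952 carried an EST name, 323 were blanks, 12 were named N/A and 1 had no name. The EST spots stood for 11926 clones, of which 26 were spotted more than once and averaged. No spot was flagged in the files. Recorded local background was 0 for most spots, so a spot was taken as above background when either channel exceeded the 95th percentile of the blank spots on that array. On the 11 arrays, 80.2% to 98.0% of EST spots passed. A spot was kept if it did so on at least 2 arrays of every experiment, which left 9180 clones. The number of arrays limits the precision.

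Intensities were background corrected with normexp (offset 50), and log2 ratios were normalized by loess within each array, with blanks and unnamed spots at weight 0, in limma 3.58.1 under R 4.3.3. All arrays entered 1 limma fit (lmFit and eBayes) with a coefficient per experiment and a shared dye term per clone, which left 6 residual degrees of freedom plus 6.14 prior degrees of freedom. A clone was called at a Benjamini-Hochberg adjusted p under 0.05. Differences between experiments were contrasts in the same fit. Because 3 experiments and the unmeasured comparison of La plus DMSO with DMSO close a loop, that comparison was computed as the W7 ratio minus the other 2 ratios. The dye term itself was called for 0 clones.

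Sets of clones called in one experiment were followed on the arrays of the others as the median log2 ratio per array, then the mean ± SD over arrays. They were tested with fry and with camera, with a preset and with an estimated correlation between clones. More tests were computed than were kept. P-values were adjusted over the 14 kept, all on arrays that did not choose the set. In fry the set's clones are tested for moving, on balance, one way. A set's calls used the dye term and the spread shared with the other arrays, so a set from the 3 TFP arrays alone was also followed. Following and testing these clone sets was not planned and was chosen after the data had been seen. Correlations were computed across clones, which are not independent replicates, and were set beside 100 simulations with no effect, which show what the shared dye term adds.

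The spot names are EST identifiers. The supplied gene table of 38312 genes matched 0 of them, and the files do not pair them with gene names, so results are given for clones. The 20 gene lists and the promoter motif test fixed before the data were examined were not applied, nor was the mean over clones of a gene. Several clones can stand for 1 gene. The rule for named clones, fixed before the data were examined, took up to 12 clones each way with the largest change among those called, with the same sign on all 3 arrays and above background on each. With no gene names, the first 2 each way in TFP against DMSO are named and followed through the other experiments.

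The 11 arrays were placed by hand in 5 scan sets, from the image folders given in the scanner headers. Set 1 held W7 array 1, set 2 held W7 against La plus W7 arrays 1 and 2, set 3 held TFP arrays 1 and 2 and La plus W7 arrays 2 and 3, set 4 held array 3 of TFP, of W7 and of W7 against La plus W7, and set 5 held La plus W7 array 1. All arrays of set 3 had the test RNA in Cy5 and all others in Cy3, so dye orientation and this scan set cannot be told apart. With the scan set as a fixed block only differences between experiments can be fitted. W7 array 1 and La plus W7 array 1 are each alone in a scan set, so they do not inform these differences. W7 array 3 is then set against La plus W7 arrays 2 and 3 through the TFP arrays, which chose the 2 TFP sets. For these sets only medians are given from that fit.

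The fit was tested on simulated data with the spread of the real clones, taken as the same on all arrays. In these data 100 of 9180 clones changed by a log2 ratio of 1 and 100 by 2. For TFP against DMSO it recovered 44% of the clones changed by a log2 ratio of 1 and 94% of those changed by 2, for W7 against DMSO 10% and 71%, for W7 against La plus W7 22% and 79%, and for La plus W7 against La plus DMSO 42% and 91%. Alternatives fixed beforehand covered background correction, normalization, the filter, the dye term, separate fits, a block for the replicate number, array weights, the variance model, the deposited ratios, the threshold, each array left out and each W7 against La plus W7 array turned. Figures were drawn with matplotlib.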

Results

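Transcript ratios were measured for 9180 EST clones on 11 2-colour arrays of Arabidopsis seedlings, which covered the response to 2 calmodulin antagonists and the effect of a lanthanum pretreatment on the W7 response. There were 3 arrays for TFP against DMSO, 2 for W7 against DMSO with 1 more known only from the authors' deposited ratio, 3 for W7 against La plus W7, and 3 for La plus W7 against La plus DMSO. The median EST spot had an intensity of 667 to 2659 in the scanner's units, against 95th percentiles of the blank spots of 84.1 to 704. The SD of the log2 ratios over clones was 0.52, 0.79 and 0.48 on the TFP arrays, 0.61 and 0.86 on the W7 arrays, 0.58, 0.85 and 0.43 on the W7 against La plus W7 arrays, and 0.47, 0.30 and 0.33 on the La plus W7 arrays. Across clones, replicate arrays correlated at a mean r of 0.34 for TFP (3 pairs), 0.34 for W7 (1 pair) and 0.38 for W7 against La plus W7 (3 pairs), and at -0.03 for La plus W7 against La plus DMSO (3 pairs). Clones are not independent replicates.

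**Figure D1:**
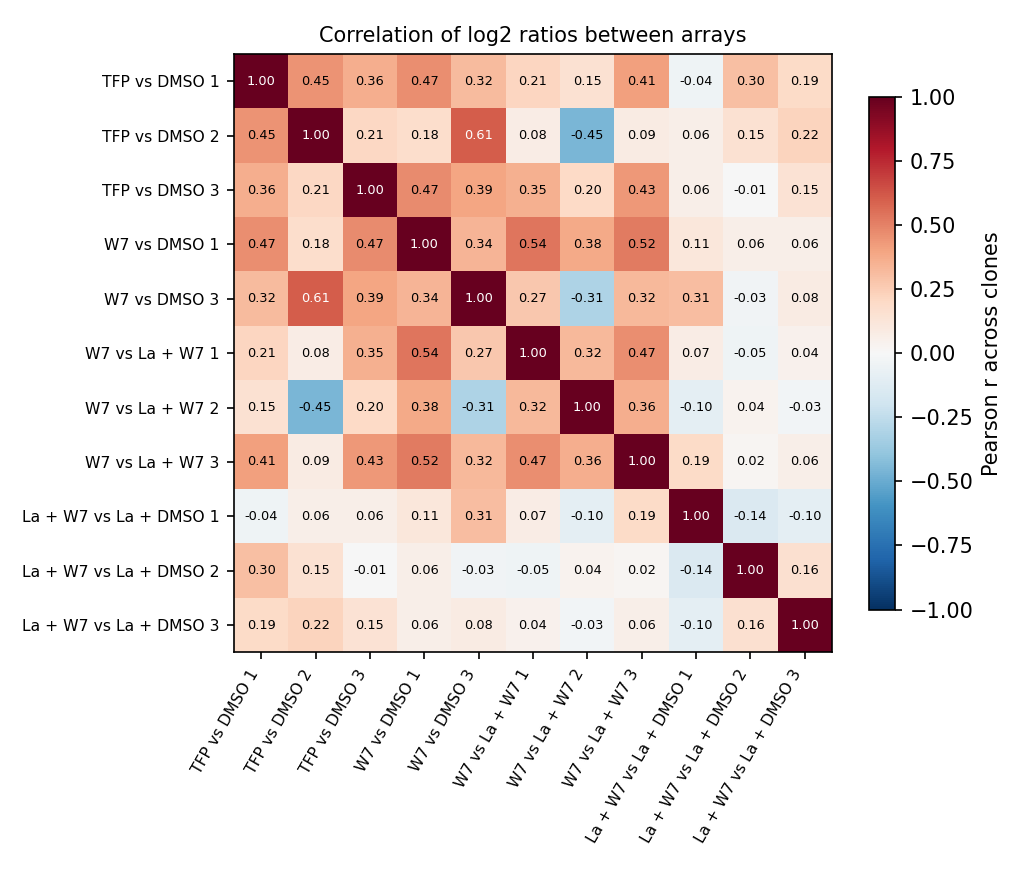
Pearson correlation across 9180 clones of the log2 ratios (test over control) of each pair of the 11 arrays, named by experiment and replicate number. Arrays of the first 3 experiments correlate mostly above 0, apart from TFP array 2 and W7 against DMSO array 3 with W7 against La plus W7 array 2 (r = -0.45 and -0.31), and the La plus W7 arrays lie between -0.14 and 0.16 among themselves.

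The first comparison asked which transcripts respond to TFP within 1 h. TFP raised 208 clones and lowered 15 against DMSO. Among the raised clones the median fitted log2 ratio was 1.53, and 195 of the 208 had a log2 ratio of at least 1. Among the lowered clones the median was -1.06, and 9 of the 15 reached -1. The largest rises were those of clone T22041, with a log2 ratio of 3.66 (SE 0.19, adjusted p = 2.1e-06), and clone T43596, with 3.29 (SE 0.20, adjusted p = 6.7e-06). Both were positive on 3 of 3 arrays. The largest falls were those of clone N97158, at -1.91 (SE 0.42, adjusted p = 0.033), and clone N97015, at -1.81 (SE 0.34, adjusted p = 0.014), each negative on 3 of 3 arrays. All of these p-values come from the limma fit. The call of N97158 was lost without any single TFP array (adjusted p = 0.079, 0.22 and 0.062 without arrays 1, 2 and 3), as was that of N97015 (0.075, 0.052 and 0.38), and the call of N97158 was also lost with the trend and robust variance model (0.12), with print-tip loess (0.051), without W7 against La plus W7 array 1 (0.052) and without La plus W7 arrays 1, 2 and 3 (0.0501, 0.059 and 0.059). The files do not pair clone names with gene names. The count of 223 clones fell to 94, 113 and 70 without TFP arrays 1, 2 and 3, and the authors' deposited ratios gave 273 rises and 62 falls. It was 514 with array weights.

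The same question was put for W7. W7 raised 193 clones and lowered 56, and all of these had a log2 ratio of at least 1 in size. The median log2 ratio was 1.98 for the raised and -1.58 for the lowered clones. T22041 rose by 4.43 (SE 0.27, adjusted p = 1.1e-05) and T43596 by 4.15 (SE 0.28, adjusted p = 2.1e-05), and N97158 fell by 2.65 (SE 0.59, adjusted p = 0.033). The call of N97158 was lost without W7 array 1 or 3 (adjusted p = 0.063 and 0.33), TFP array 3 (0.17) or La plus W7 array 2 or 3 (0.052 and 0.056), with array weights (0.066) and with the trend and robust variance model (0.11). N97015 had a log2 ratio of -1.07 (SE 0.48) that missed the threshold (adjusted p = 0.33), and its arrays differed: the ratio was -2.13 without array 3 and -0.01 without array 1, and its test channel was above the blanks on 1 of the 2 arrays. The calls rested on 2 arrays with the test RNA in Cy3. With the deposited ratios, which add array 2, 399 clones rose and 239 fell, and 246 of the 249 clones were called again in the same direction. N97015 was called with these ratios, at -1.44 (SE 0.33, limma adjusted p = 0.017). The count was 53 without W7 array 3, 68 without TFP array 3, 140 without La plus W7 array 2 and 163 without La plus W7 array 3. It was 421 without the dye term, but 88 with array weights (85 rises, 3 falls) and 143 with the trend and robust variance model (136 rises, 7 falls). The W7 calls also changed through the common fit when an array of W7 against La plus W7 was turned. With array 1, 2 or 3 of that experiment turned, 7, 20 and 0 clones were called for W7. T22041 and T43596 were then not called for W7 (limma adjusted p = 0.13 to 0.22), with log2 ratios of 3.22 to 3.46. The SE of T22041 was then 0.93 to 0.97, beside 0.27 as reported. A turned array opposes its replicates and widens the spread that all comparisons share. The lost calls therefore do not tell how that array was oriented.

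**Figure D2:**
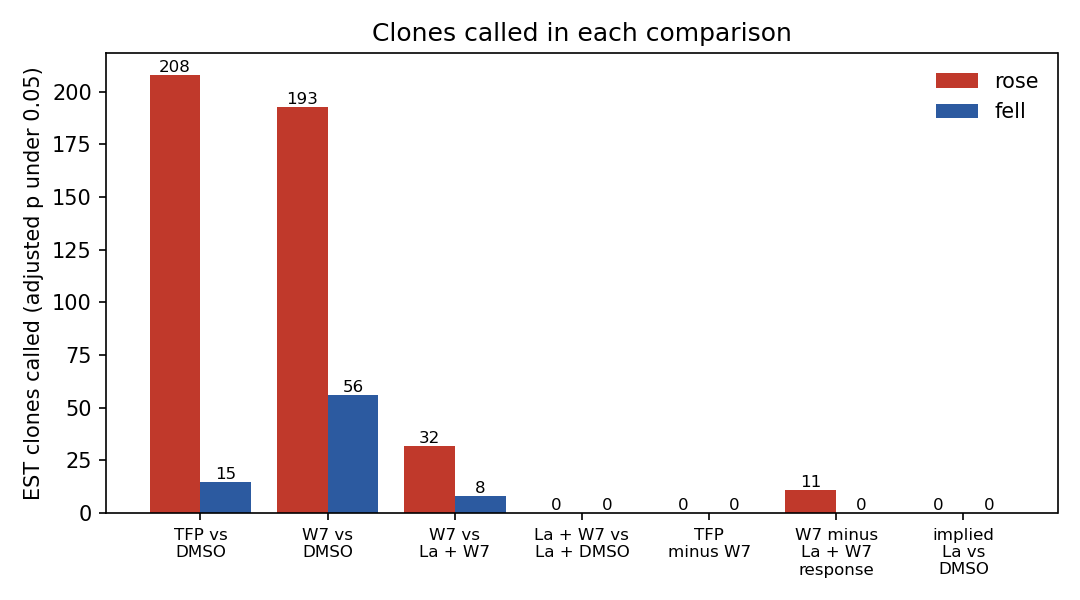
Number of clones called at adjusted p under 0.05 (vertical axis, count of EST clones) in each of the 4 experiments and the 3 differences computed from them, with rises and falls as separate bars. Rises outnumber falls among the called clones of the 3 experiments with calls (208 against 15, 193 against 56 and 32 against 8), and La plus W7 against La plus DMSO has 0 calls.

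Both antagonists were then set side by side. Of the clones TFP raised, 128 were also raised by W7, where independent lists would share 4.37, and 6 clones were lowered by both, where independent lists would share 0.092. No clone was called in opposite directions by TFP and W7. All 208 clones TFP raised had a fitted W7 ratio above 0, and 175 of them had one of at least 1. The 80 of them that were not called for W7 had a median W7 log2 ratio of 1.06 ± 0.02 (SD, n = 2 arrays), with 1.26 ± 0.05 on the TFP arrays that chose them (n = 3). Of the 65 clones raised by W7 and not called for TFP, 64 had a fitted TFP ratio above 0. All 56 clones W7 lowered had a fitted TFP ratio below 0, with a median of -0.73 ± 0.32 on the TFP arrays (SD, n = 3). Over all clones the fitted log2 ratios of TFP and W7 correlated at r = 0.73 (Spearman 0.58), and simulations with no effect gave a mean of -0.13 from the shared dye term. The correlation was 0.47 without TFP array 3 and 0.53 without W7 array 3. Single arrays agreed less, with 6 pairs at 0.18 to 0.61 (mean 0.41). The highest pair was TFP array 2 with W7 array 3, which is taken up again under other observations. The difference between the TFP and W7 responses, tested directly in limma, was called for 0 clones. An unadjusted p under 0.05 was found for 210 clones, 2.29% of those tested and less than the 5% that no difference would give. This does not show equal responses, since the 95% interval of the difference had a median half-width of 0.96 on the log2 scale per clone. With the scan set as a fixed block the difference rests on TFP array 3 and W7 array 3 alone, which share a scan set. The clones TFP raised had medians of 1.35 for TFP array 3 and 1.67 for W7 array 3, with 1 array each and no test.

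**Figure D3:**
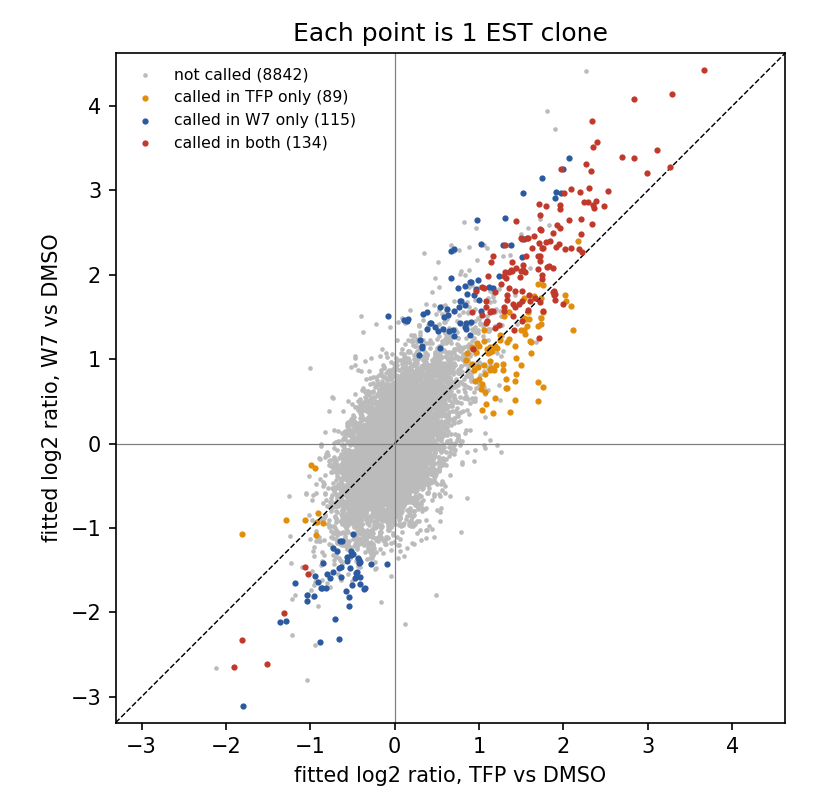
Fitted log2 ratio of each of 9180 clones in TFP against DMSO (horizontal axis) and in W7 against DMSO (vertical axis), coloured by where the clone was called at adjusted p under 0.05. The dashed line marks equal ratios, and the clones called in both experiments lie to the upper right and the lower left.

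W7 against La plus W7 asked how the transcripts of W7-treated seedlings differ when La was given first. In seedlings without La, 32 clones were higher and 8 were lower, with median log2 ratios of 1.72 and -1.90. At an unadjusted p under 0.05 the balance was the other way, with 456 clones higher and 558 lower. T22041 was higher by 2.97 (SE 0.24, adjusted p = 0.00022) and T43596 by 2.71 (SE 0.25, adjusted p = 0.00054), each on 3 of 3 arrays. N97158 had a log2 ratio of -1.63 (SE 0.51, adjusted p = 0.20) and N97015 of -0.81 (SE 0.41, adjusted p = 0.52). With array weights N97158 was called, at -1.83 (SE 0.38, limma adjusted p = 0.022). Of the 32 higher clones, 30 were also raised by W7 and 27 by TFP, where independent lists would share 0.67 and 0.73. The clones raised in all 3 experiments numbered 26, against 0.015 for independent lists, and 0 were lowered in all 3. Independent lists are not the no-change case for W7 and W7 against La plus W7, because both use the same dye term and have the same dye orientation. Over all clones their fitted ratios correlated at r = 0.36, and simulations with no effect gave a mean of 0.31 and a highest value of 0.35. The simulations hold noise alone, so their value is not a share of the 0.36. Without the dye term the correlation was 0.31, though all these arrays had the same dye orientation. The 6 pairs of arrays ranged from -0.31 to 0.54 (mean 0.29). With the dye term the value ran from 0.08 without W7 array 1 to 0.62 without W7 array 3. It was 0.21, 0.59 and 0.23 without arrays 1, 2 and 3 of W7 against La plus W7. The clones that TFP raised had a median log2 ratio of 0.84 ± 0.05 here (SD, n = 3 arrays), and those TFP lowered had one of -0.85 ± 0.29. In fry both sets moved in the direction of TFP (adjusted p = 1.2e-05 and 0.0011), as they did in camera with an estimated correlation (adjusted p = 6.6e-05 and 0.0063).

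The counts of this comparison depended on the dye term, and all of its arrays had the same dye orientation. Without the term 308 clones were called, 172 higher and 136 lower, among them all 40 called with it. The 40 calls fell to 3 and 14 without arrays 1 and 2 of this experiment, to 14 and 4 without TFP arrays 1 and 3, and to 8, 7 and 7 without La plus W7 arrays 1, 2 and 3, and rose to 80 without either W7 array. The deposited ratios gave 67 higher and 45 lower, array weights 123 and 104, print-tip loess 12 and 5, and the trend and robust variance model 6 and 0. If any 1 of the 3 arrays was in truth a dye swap, as the design text has it, the calls would not stand. With any of them turned, 0 clones were called. As labelled the 3 arrays correlated positively with each other (r = 0.32 to 0.47). This alone cannot decide, since a dye bias common to them would also give it. The clones TFP raised, chosen without these arrays except through the shared dye term and spread, had medians of 0.85, 0.78 and 0.88 on them. They also rose on the TFP arrays with the test RNA in Cy5 (1.61 and 1.63) and in Cy3 (1.35). For these clones the values argue against a swap of 1 array. The count of 26 clones changed in the same direction in all 3 experiments became 90 without the dye term, 54 with the deposited ratios and 56 with array weights, but 12 with print-tip loess and 6 with the trend and robust variance model. They numbered 9 and 3 without TFP arrays 1 and 3, 3, 13 and 14 without arrays 1, 2 and 3 of this experiment, and 6, 6 and 7 without the La plus W7 arrays 1, 2 and 3.

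La plus W7 against La plus DMSO asked what W7 does in seedlings that had been given La. The limma fit called 0 clones, and 220 clones had an unadjusted p under 0.05, of which 174 were higher. These are 2.40% of the clones tested, less than the 5% that no change would give. Array weights gave 1 call. T22041 had a log2 ratio of 0.74 (SE 0.19) and T43596 of 0.83 (SE 0.20), both positive on 3 of 3 arrays but with an adjusted p of 1.00. N97158 stood at -0.15 (SE 0.42) and N97015 at -0.19 (SE 0.34). In the simulation of this experiment 42% of the clones with a log2 ratio of 1 and 91% of those with a log2 ratio of 2 were called. Changes of the larger size were thus mostly detectable there and smaller ones often were not. The simulation gave each clone the same spread on all arrays, so these rates need not hold for the real La plus W7 arrays. The clones that TFP raised had a median log2 ratio of 0.29 ± 0.10 (SD, n = 3 arrays), a ratio of 1.23, and 174 of the 208 had a fitted ratio above 0 while 3 reached 1. This small rise of the set passed fry (adjusted p = 0.0020) and camera with an estimated correlation (adjusted p = 0.00088). The clones W7 raised behaved alike, at 0.28 ± 0.10 (fry adjusted p = 0.0074, camera with an estimated correlation adjusted p = 0.0035). The 15 clones TFP lowered stood at -0.17 ± 0.07 (fry adjusted p = 0.57), and the 56 clones W7 lowered at -0.05 ± 0.13 (fry adjusted p = 0.93).

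Whether La changed the W7 response was tested as the difference between the W7 responses without and with La. The clones that TFP raised, chosen without use of the W7 arrays except through the shared dye term and spread, had a median log2 ratio of 1.65 ± 0.04 to W7 without La (SD, n = 2 arrays) and 0.29 ± 0.10 with La (n = 3), which are ratios of 3.13 and 1.23. The fitted difference had a median of 1.56 (fry adjusted p = 5.2e-06, camera with an estimated correlation adjusted p = 2.0e-05). The lowest W7 array stood at 1.62 and the highest La plus W7 array at 0.41. An exact permutation test of the array medians gave p = 0.1 (two-sided), the smallest that 2 against 3 arrays allow. For the clones TFP lowered, the medians were -1.13 without La and -0.17 with La, and the fitted difference had a median of -1.22 (fry adjusted p = 0.0021). Clone by clone, 11 clones responded more to W7 without La and 0 responded less, at adjusted p under 0.05 in limma. All 11 were raised by W7 and by TFP, and 6 of them were among the 32 higher in W7 against La plus W7. Their median ratio was 9.85 to W7 without La and 1.36 with La, a gap that the choice of these clones enlarges. Their median log2 ratio was 3.19 and 3.41 on W7 arrays 1 and 3. On W7 array 2, which did not choose them, it was 2.53 in the deposited ratios.

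With the scan set as a fixed block, which left 3 residual degrees of freedom, 0 of the 11 clones were called. In that fit the difference rests on W7 array 3 alone, set against La plus W7 arrays 2 and 3 through the TFP arrays. W7 array 1 and La plus W7 array 1 are each alone in a scan set and add nothing to it. The 11 clones had a median difference of 3.04 in the reported fit (median SE 0.40) and 3.09 with the block (median SE 0.62). They were chosen for this difference on the same arrays, so its size in the second fit is no support. The clones TFP raised had a median difference of 1.54 with the block, and those TFP lowered had one of -1.45. Both values use the TFP arrays that chose these sets, so they are not an independent check. The scan set that held TFP arrays 1 and 2 and La plus W7 arrays 2 and 3 allows only TFP, not W7 without La, to be set against La plus W7. There the difference was called for 0 clones in limma, with 859 at an unadjusted p under 0.05. The clones TFP raised had medians of 0.25 and 0.41 on these La plus W7 arrays, beside 1.61 and 1.63 on the TFP arrays that helped to choose them. The count of 11 was 0 and 2 without La plus W7 arrays 1 and 2, 7 without array 3, 3 and 6 without TFP arrays 1 and 3, 4 without W7 array 3 and 33 without W7 array 1. It was 52 without the dye term, 76 with the deposited ratios and 17 among clones above the blanks in both channels, but 4 with median centring and 1 with the trend and robust variance model.

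**Figure D4:**
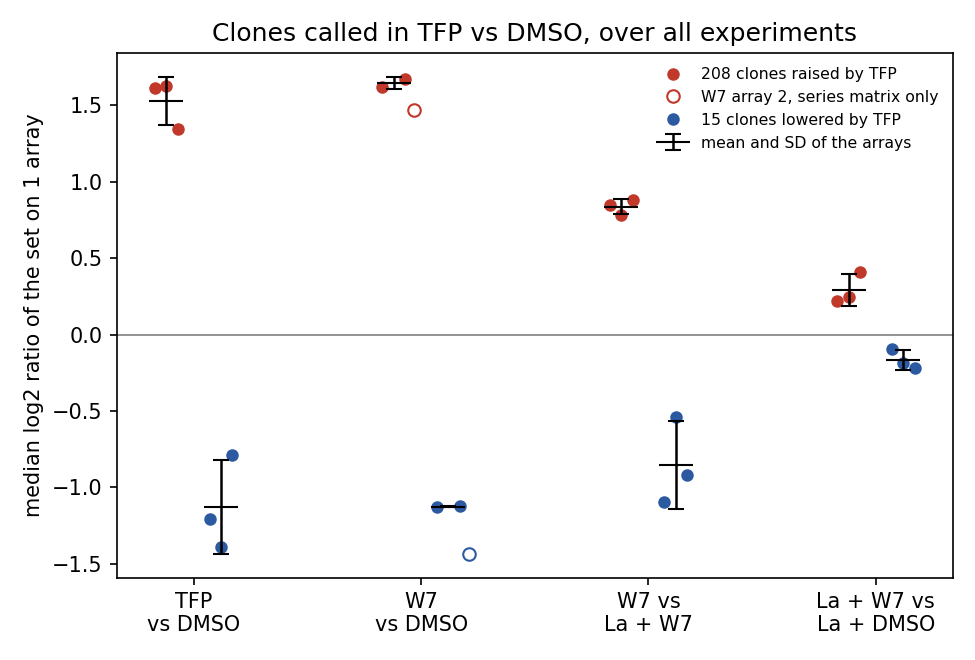
Median log2 ratio (vertical axis) on each array of the 208 clones raised by TFP (red) and the 15 clones lowered by TFP (blue) in the 4 experiments, with the mean and SD of the scanner arrays as black bars and W7 array 2, known only from the deposited ratios, as open circles. The raised clones sit at 1.35 to 1.67 on the TFP and W7 scanner arrays, at 0.78 to 0.88 in W7 against La plus W7 and at 0.22 to 0.41 in La plus W7 against La plus DMSO.

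La plus DMSO was not set against DMSO on any array, but that ratio follows from the other 3 experiments that close the loop. It was called for 0 clones in limma, with 557 clones (6.07%) at an unadjusted p under 0.05, and the 95% interval had a median half-width of 0.97 per clone. For the clones TFP raised the fitted value had a median of 0.55 (fry adjusted p = 0.00055, camera with an estimated correlation adjusted p = 0.0010), and for those TFP lowered it was -0.39 (fry adjusted p = 0.35).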

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

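The tests of the 3-way loop were chosen after the result they measure was seen.

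The W7 response differed between seedlings without and with La for 11 clones, by a direct test of the difference, and all 11 were higher without La. The clones TFP raised show the same ordering on every array, and they also leave a gap. Their W7 ratio without La averaged 1.65, while W7 against La plus W7 (0.84) and La plus W7 against La plus DMSO (0.29) add up to 1.13, which leaves 0.52. Bright blank spots that compress ratios would make the W7 against La plus W7 array with the dimmest blanks stand well above the other 2, but it exceeded their mean by only 0.064. A dye bias of these clones would turn the gap's sign between La plus W7 arrays of opposite dyes, and the gap was 0.48 with the test RNA in Cy5 and 0.59 in Cy3. A candidate explanation is that La alone raised these clones in DMSO-treated seedlings, for which the fitted gap of 0.55 is the estimate. It stays open, because no array compared La plus DMSO with DMSO and because scan sets differ between the legs of the loop.

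Of the 12 spots named N/A, which carry no EST name and entered no comparison, 9 were above the blank level on all 11 arrays. Of the 323 blank spots 0 were, but the level was set from these same spots, so few of them could pass. None of the 12 was called in any of the 4 experiments when added to the limma fit.

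W7 against DMSO array 2 is known only from the deposited ratios. The clones TFP raised had a median log2 ratio of 1.47 there, beside 1.54 and 1.63 for arrays 1 and 3 in the same table, and this array correlated across clones with arrays 1 and 3 at 0.51 and 0.41.

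Other turnings of the arrays, in which the ratio of each array in turn is reversed, number 4 per experiment with the real one, too few for a share under 0.05. TFP against DMSO gave 223 clones in the real arrangement and at most 0 in the others (1 of 4 as large). W7 against La plus W7 gave 40 and at most 0 (1 of 4). La plus W7 against La plus DMSO gave 0 in all 4. A turned array opposes its replicates and widens the spread, which by itself lowers the counts of the other turnings. The counts therefore do not tell whether the calls arose by chance.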

How the results depend on the processing

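The 2 fits with the scan set as a block and the set medians in the fixed one were chosen after seeing the data. So were scan set 3 alone and the fits of the deposited ratios without the dye term and for 11 arrays. The set from the TFP arrays alone and every alternative for the clone sets were also chosen then. The counts for TFP minus W7 and for the implied effect of La were 0 in every alternative that gave them. The median of the clones TFP raised stayed above 0 in W7 and in La plus W7 in the 13 alternatives and 11 left-out arrays for which it was computed. Many of these could not move it, since the clones were those of the reported fit unless the set came from the TFP arrays alone. Leaving out an array of another experiment, turning a W7 against La plus W7 array or dropping the filter returns the same median. The median was not recomputed where only the fit or the threshold changed. The cause of the moves below was not tested.

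Counts are given in the order TFP, W7, W7 against La plus W7, difference of the W7 responses, and clones raised or lowered in all 3 experiments, with 223, 249, 40, 11 and 26 as reported. Without the dye term the last 4 were 421, 308, 52 and 90. The deposited ratios gave 335, 638, 112, 76 and 54, and without the dye term 375, 638, 271, 96 and 104. With array weights the first 3 were 514, 88 and 227, the last was 56, and La plus W7 against La plus DMSO had 1 call. The trend and robust variance model gave 143, 6, 1 and 6 for the last 4. At adjusted p 0.01 the 5 counts were 95, 55, 3, 2 and 3. Taking the shared W7 file with the dyes of array 2 gave 413, 110, 24 and 42 for the last 4. Print-tip loess gave 17 for W7 against La plus W7 and 12 for all 3, separate fits gave 79 for W7 against La plus W7, and the difference of the W7 responses had 4 clones with median centring, 17 among clones above the blanks in both channels and 0 with the scan set as a fixed block. Scan set 3 alone gave 464 clones for TFP.

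Turning W7 against La plus W7 array 1, 2 or 3 gave 119, 139 and 112 clones for TFP, 7, 20 and 0 for W7, and 0 each for W7 against La plus W7, the difference of the W7 responses and all 3 experiments. The clones TFP raised then stood at 0.27, 0.31 and 0.25 in that experiment and those it lowered at -0.12, -0.49 and -0.24. The correlation of W7 with W7 against La plus W7, 0.36 as fitted against 0.31 in simulations with no effect, turned to -0.23 and -0.18 when array 1 or 3 was turned.

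The correlation of W7 with La plus W7 was 0.11 as fitted, where simulations with no effect gave a mean of -0.13 and a highest value of -0.09. It was 0.26 without the dye term and in separate fits, 0.26 with the deposited ratios, 0.29 with these and no dye term, and 0.31 with the dyes of array 2 for the shared file. It reversed to -0.38 without La plus W7 array 1.

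For the clones TFP raised, the W7 ratio moved by more than its SD of 0.04 to 1.61 with print-tip loess, 1.41 with median centring, 1.55 with the deposited ratios (1.58 for 11 arrays) and 1.72 when the set came from the TFP arrays alone, and their ratio in W7 against La plus W7 was 0.79 with the deposited ratios of 12 and of 11 arrays. For the clones TFP lowered, the W7 ratio of -1.13 (SD 0.003) was -1.09 both without background correction and with local background subtracted, -0.98 with print-tip loess, -1.21 with median centring, -1.25 above the blanks in both channels, -1.24 with the deposited ratios, -1.14 for 11 arrays and -1.59 from the TFP arrays alone.

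Leaving out each of the 11 arrays gave 70 to 272 clones for TFP, 53 to 308 for W7, 3 to 80 for W7 against La plus W7, 0 to 33 for the difference of the W7 responses and 3 to 26 for all 3 experiments. The correlation of TFP with W7 ranged from 0.47 to 0.74, that of W7 with W7 against La plus W7 from 0.08 to 0.62, and that of W7 with La plus W7 from -0.38 to 0.21. Where 1 W7 array was left, it was assumed to vary like the other experiments.

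Same-numbered arrays of different experiments did not deviate together: 3 of 15 pairs correlated above 0.1 (mean r = -0.08), so the numbers were not taken as pairs. With the replicate block in the fit the 5 counts were 136, 99, 6, 2 and 5, and N97158 was called in neither TFP nor W7 (adjusted p = 0.101 and 0.102). Which limit weighs most was not tested. The gene lists, the promoter motifs and the mean over clones of a gene were not run.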

Other observations

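The tests of the pair of opposed arrays, the test of dim spots on clones bright in the W7 arrays and the fit of scan set 3 alone were chosen after the result was seen.

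TFP array 2 and W7 against La plus W7 array 2 correlated at -0.45 across clones, and TFP array 2 and W7 array 3 at 0.61. Among the 8834 clones called in none of TFP, W7 and W7 against La plus W7, these were -0.56 and 0.54, and in the brightest 1836 clones they were -0.59 and 0.74, so the pattern is not that of the called clones. Uneven hybridisation between print blocks is argued against by a correlation of -0.44 after print-tip loess. W7 against La plus W7 array 2 correlated at 0.32 and 0.36 with the other 2 arrays of its experiment. This alone does not decide whether its channels were exchanged, since a dye bias common to the 3 arrays would also give it. The clones TFP raised had a median of 0.78 on this array, beside 0.85 and 0.88 on arrays 1 and 3. For these clones this argues against an exchange. The arrays lie in different scan sets, and no biological explanation was tested.

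Rises made up 93.3% of the clones called for TFP. That dim spots hid falls cannot be told from the 91.2% among clones above the blanks in both channels on all 11 arrays, since this filter also drops clones that TFP lowered below the blanks. Among the 5674 clones at least 4 times the blank level in the DMSO channel of both W7 arrays, a choice that does not use the TFP arrays, the share was 92.1% (128 rises, 11 falls), which argues against hidden falls for these clones and leaves them open for dimmer ones. An intensity-dependent shift by the normalization is argued against as the whole cause by 92.5% with median centring. The size of the excess depended on the fit: rises made up 69.8% with scan set 3 alone, 77.8% with array weights and 81.5% with the deposited ratios, and 687 clones rose against 353 that fell at an unadjusted p under 0.05 (417 against 231 among the bright clones), so a larger share of transcripts raised than lowered after 1 h stays open.

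The clones that responded had a higher average intensity than most. The median average log2 intensity was 11.14 for the clones TFP raised and 11.50 for those W7 lowered, which are at the 65.5th and 72.4th percentile of all clones tested. For the clones TFP lowered it was 10.95, the 61.6th percentile. This average covers both channels, so a rise itself lifts it and a fall lowers it.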
